A study of Homo sapiens with 18 samples.

How the data were processed

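Bulk RNA was measured in 18 libraries of polyA RNA from ventral forebrain organoids, which are neural tissues grown in suspension from pluripotent stem cells. Per the labels' protocols, the organoids came from the H9 human embryonic stem cell line, and were patterned toward ventral fates from day 10 with 100 ng/mL of the morphogen SHH and 1 µM of purmorphamine, an agonist of the same pathway. Dosing began at day 83 and was repeated daily for 1 week, and each dose was followed by a change of medium after 1 h. Dopamine or cocaine was given at 1 µM in 100 µM ascorbic acid, an antioxidant that was also the vehicle control. Where the inhibitor of reactive oxygen species (ROS) was used, 100 µM acetylcysteine, a thiol antioxidant, was added before each dose. The labels' treatment field put the libraries into 6 groups of 3, which were control, dopamine and cocaine, each with and without the inhibitor. The labels give no batch, day or replicate number shared between groups, so libraries were numbered 1 to 3 within a group in deposit order, which only names them. Another cell line mentioned in the series' design text was not analysed here. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

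The raw counts of reads per gene were deposited by the authors as whole numbers without normalization, and a TPM value per gene and library was deposited beside them, scaled to a sum of 1000000 per library. The build was GRCh38/hg38 per the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation version are not given in the sources used here. Deposited counts therefore cannot separate antisense or overlapping genes, and counts of genes with near-identical copies are uncertain, among them HSPA6, HSPA1A, HSPA1B, FTL, histones, metallothioneins and ribosomal proteins. The authors also deposited 5 tables of their own comparisons, with a log2 fold change, a p-value and a false discovery rate (FDR) p-value per gene, per the file headers. Every gene in these tables had an absolute log2 fold change of at least 1 and an FDR of at most 0.05. The test behind them is not given in the sources used here. Their headers name the treated group and not its comparator, which was found by matching each table to ratios of group mean TPM; the median difference was 0.014 to 0.044 for the best comparator and 0.18 to 0.54 for the next.

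The count table held 53853 genes, of which 28 had a name that a spreadsheet had turned into a date and 2 names were duplicated; 26 of the date names were among the genes tested. Total counts ran from 23789195 to 30327891 reads per library, and 23901 to 24573 genes had at least 1 read. At that depth a gene at 5 CPM (counts per 1000000 reads) rested on more than 100 reads per library. The 13 protein-coding genes of the mitochondrial genome were at 0 in each of the 18 libraries and were not tested. No pair of libraries within a group agreed within sampling noise: over genes with at least 20 reads, the chi-square per gene was 3.54 to 21.7 and the correlation of log values 0.9848 to 0.992, so each library was counted once.

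Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Counts were scaled by trimmed mean of M values (TMM, factors 0.975 to 1.016), and 18913 genes passed the expression filter of edgeR with a minimum count of 10. A negative binomial model with 1 mean per group was fitted to all 18 libraries, so that the 6 groups shared an estimate of the spread, and 12 contrasts were tested with the robust quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The contrasts were dopamine and cocaine against control, the same with the inhibitor, the inhibitor alone against control, each drug with the inhibitor against the drug alone and against control, cocaine against dopamine, and the drug by inhibitor interactions. Levels are CPM with TMM scaling, given as mean ± SD, and fold changes carry the standard error (SE) of the fit.

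Gene lists were tested as sets with camera from limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Camera was repeated with the correlation estimated from the data for each list, and that adjusted p is given as "with an estimated correlation". Of the 40 lists, 38 had at least 5 measured members, and 17 of the 40 held markers of cell types that an organoid can contain. The mitochondrially encoded genes (0 of 13 measured) and the pluripotency markers (3 of 8 measured) were not tested. For each list the number of members called over all genes is given beside the number called when p was "adjusted over the list alone".

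The design, the tests, the gene lists, the rule for naming genes and all alternatives except the removal of a length trend were fixed before the data were examined. The rule named, for each comparison with a vehicle of the same inhibitor state, up to 10 genes that rose and 10 that fell with the largest fold change among called genes with a mean of at least 5 CPM, no overlap between replicates of the 2 groups, and a symbol outside the uncharacterized and antisense classes. Up to 5 each way were named elsewhere, and the 5 smallest p where no gene passed. It also named a panel of 21 genes of dopamine handling, early response and redox state in both drug comparisons, up to 4 members of each list described, and up to 5 genes each way from each of the authors' deposited tables. The condition of no overlap could not be applied to interactions. SLC6A3, which encodes the dopamine transporter, was below the expression filter, so 20 of the 21 panel genes were tested. Results for some genes that the rule named are not reported here. Gene positions are the spans in the RefSeq annotation of GRCh38.p14, matched by symbol; HIST1H1C had no match under that symbol.

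The alternatives were DESeq2 1.42.0 in place of edgeR, relative log expression (RLE) size factors in place of TMM, no filter on low counts, a fit with only the groups compared, limma voom with sample quality weights, and each library left out in turn. Removal of each library's trend on transcript length was added after the data were seen. The tests were run on simulated counts drawn from the real means and library sizes with 200 genes changed. Each gene was drawn separately, so these counts hold no outlying library and no shift shared by many genes. The shares and false calls that follow are therefore no error rate for the calls in the real libraries. For dopamine against control (18709 genes) 56.7%, 76.1% and 80.3% of genes changed by 1.5, 2 and 3 fold were called, with 10 unchanged genes called. For cocaine against control (18699 genes) the shares were 55.2%, 71.6% and 80.3%, with 3 unchanged genes called. For the dopamine by inhibitor interaction (18709 genes) they were 40.3%, 65.7% and 74.2%, with 4. With a length trend planted in the cocaine comparison (18757 genes), 5469 unchanged genes were called before its removal and 10 after it. A slope of 0.5 between the cocaine responses was returned as 0.49 after correction for noise and as 0.39 without it (12623 genes).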

Results

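Gene expression was measured in H9 organoids of ventral forebrain type after a week of daily exposure to dopamine, a monoamine neurotransmitter, or cocaine, a blocker of monoamine transporters. Each of the 6 groups held 3 libraries: control, dopamine, cocaine, and each of these with the ROS inhibitor acetylcysteine. Total reads ran from 23789195 in dopamine + inhibitor 3 to 30327891 in dopamine 3. The first principal component of the 2000 most variable genes held 18.9% of the variance and the second 10.6%.

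The libraries differed in markers of non-neuronal and regional cell types within as well as between groups, as shown by genes picked after their values were seen. TTR, the thyroid hormone carrier made by choroid plexus, was at 1.32, 7.44 and 21.1 CPM in the controls, and at 198, 29.4 and 141 CPM with cocaine. With dopamine it was at 50.3, 61.8 and 42.3 CPM, and in control + inhibitor at 79.7, 5.92 and 139 CPM. HOXB9, a gene of posterior identity, reached 87.6 CPM in cocaine 2. The proliferation gene MKI67 was at 108 CPM in cocaine 3 and 126 CPM in cocaine + inhibitor 1, and between 41.7 and 45.7 CPM in the controls. PMEL, a pigment cell gene, stood at 29.4 CPM in dopamine + inhibitor 3. The mitochondrial ribosomal RNA gene RNR2 took 0.760% to 0.785% of reads in the controls, 0.856% to 0.894% with dopamine and 0.857% to 0.933% with cocaine.

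Dopamine against control asked how a week of dopamine changed transcription. Dopamine raised genes of the cellular stress response and lowered a smaller set of genes. HSPA6, a heat-inducible HSP70 chaperone (chromosome 1, 161524540 to 161526894), rose from 2.04 ± 0.683 to 9.98 ± 1.24 CPM (SD, n = 3; fold change 4.9, adjusted p = 0.0147). ADM, which encodes the hypoxia-induced peptide adrenomedullin (chromosome 11, 10305073 to 10307397), rose from 4.65 ± 0.586 to 12.1 ± 2.45 CPM (adjusted p = 0.027). NKX2-2, a homeodomain factor of the ventral neural tube (chromosome 20, 21511017 to 21522689), fell from 26.4 ± 5.72 to 12.1 ± 3.86 CPM (adjusted p = 0.0383). Of 18913 genes tested, 133 were called by edgeR, 105 higher and 28 lower, with a median absolute log2 fold change of 0.388, and 14 of them changed by at least 1 on the log2 scale.

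Among the other genes with the largest rises were the linker histone gene HIST1H1C (log2 fold change 1.42, SE 0.24), the decoy receptor gene TNFRSF10D (1.07, SE 0.21) and the glycogen-targeting phosphatase subunit gene PPP1R3C (0.91, SE 0.14). The stress transcription factor genes ATF3 and DDIT3 rose by 0.85 (SE 0.16) and 0.72 (SE 0.13), with adjusted p of 0.0233 and 0.0181. DDIT3, also known as CHOP, went from 11.6 ± 0.887 to 19 ± 2.12 CPM (n = 3). BHLHE40, a repressor of the circadian and hypoxic programs, rose by 0.62 (SE 0.11), CCDC9 by 0.61 (SE 0.09) and the telencephalic adhesion gene ICAM5 by 0.56 (SE 0.11). Lower genes included the basement membrane collagen COL15A1 (-0.86, SE 0.17), the pseudogene FAR2P1 (-0.66), the chemokine receptor ACKR1 (-0.55), FBXL6 (-0.51), NBEAL2 (-0.49) and TMEM266 (-0.47). The R-type calcium channel gene CACNA1E (chromosome 1, 181317699 to 181808084) fell from 407 ± 10.5 to 298 ± 31.1 CPM, and the semaphorin co-receptor gene NRP1 from 102 ± 1.85 to 75 ± 11.5 CPM.

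The stress lists moved together. In the integrated stress response list, all 18 members had a positive fold change with a median of 0.24. Of these 4 rose over all genes and 11 adjusted over the list alone (adjusted p = 1.18e-11, and adjusted p = 0.0357 with an estimated correlation). DDIT4, an inhibitor of the growth kinase mTOR (chromosome 10, 72273924 to 72276036), rose from 155 ± 11.1 to 210 ± 5.55 CPM, and MTHFD2 and SESN2 by 0.36 each on the log2 scale. All 13 heat shock genes were positive with a median of 0.2. HSPH1 rose (0.29, adjusted p = 0.0177) and 11 passed adjusted over the list alone (adjusted p = 5.47e-10, and adjusted p = 0.0357 with an estimated correlation). CRYAB, a small heat shock protein, was at 9.88 ± 2.39 against 2.82 ± 0.425 CPM (adjusted p = 0.0693). Of 15 genes of the unfolded protein response, which expands protein folding in the endoplasmic reticulum, 4 rose and 8 adjusted over the list alone (median 0.17, adjusted p = 5.47e-10, and adjusted p = 0.0928 with an estimated correlation). They were HERPUD1 (0.32), DNAJB9 (0.41), DNAJC3 (0.45) and HSPA5 (0.3), the major endoplasmic chaperone, at 479 ± 12.7 against 388 ± 10.2 CPM.

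Hypoxia and glycolysis genes had a median of 0.17, with 4 of 27 called and 12 adjusted over the list alone (adjusted p = 3.12e-07, and adjusted p = 0.335 with an estimated correlation). They were the glucose transporter gene SLC2A3 (0.41), P4HA1 (0.39), BHLHE40 and ADM. In the list of p53 targets, 2 of 17 rose and 6 adjusted over the list alone (median 0.2, adjusted p = 2.41e-05, and adjusted p = 0.335 with an estimated correlation). These were RRM2B (0.54) and the stress cytokine gene GDF15 (1.84, SE 0.37), and CDKN1A was at 0.46 (adjusted p = 0.0515). Immediate early genes, which respond to neuronal activity and to stress, had 2 of 17 called and adjusted over the list alone 8 higher and 1 lower (median 0.26, adjusted p = 0.000584, and adjusted p = 0.113 with an estimated correlation). ATF3 and FOSB were the called members. FOSB was at 2.22 ± 0.27 against 0.783 ± 0.431 CPM (adjusted p = 0.0392). Of 21 NRF2 antioxidant targets the iron storage gene FTL alone rose, also adjusted over the list alone (0.47, adjusted p = 0.00367; list median 0.04, adjusted p = 0.0118, and adjusted p = 0.233 with an estimated correlation). Ribosomal protein genes had a median of 0.1 and nuclear oxidative phosphorylation genes 0.06, with 0 members called over all genes or adjusted over the list alone (adjusted p = 3.07e-06 and 0.00612, and adjusted p = 0.648 and 0.578 with an estimated correlation).

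Lists of receptor, synaptic and ventral forebrain genes lay below 0 with dopamine, while the pan-neuronal list did not pass (median -0.07, 0 of 16 called over all genes or adjusted over the list alone, adjusted p = 0.0781). All 20 glutamate receptor genes were negative (median -0.18; 0 called, and 2 lower adjusted over the list alone; adjusted p = 0.000129, and adjusted p = 0.335 with an estimated correlation). The metabotropic receptor gene GRM5 was at -0.46 (adjusted p = 0.104). Presynaptic and synaptic genes had a median of -0.15 (0 of 28 called, and 5 lower adjusted over the list alone; adjusted p = 4.85e-06, and adjusted p = 0.524 with an estimated correlation). GABA receptor genes had -0.18 (0 of 13, and 1 lower adjusted over the list alone; adjusted p = 0.00383, and adjusted p = 0.578 with an estimated correlation). The ventral forebrain and interneuron list had a median of -0.45 and 0 of 20 called, against 4 lower adjusted over the list alone (adjusted p = 1.25e-05, and adjusted p = 0.237 with an estimated correlation). Its members NKX2-1 and DLX1, factors of ventral progenitors and interneurons, were at -3.06 (SE 0.82, adjusted p = 0.104) and -1.1 (SE 0.3, adjusted p = 0.114). NKX2-1 was scarce, at 1.47, 0.707 and 1.12 CPM in the controls and 0.216, 0.0698 and 0.0992 CPM with dopamine. Both levels are under the 5 CPM minimum of the naming rule. In the oligodendrocyte list, OLIG1 fell from 5.45 ± 0.858 to 2.15 ± 0.692 CPM (adjusted p = 0.0141), and adjusted over the list alone 1 of 10 members was higher and 2 lower (median -0.28, adjusted p = 0.00612, and adjusted p = 0.0928 with an estimated correlation). Beside these, choroid plexus genes had a median of 0.62 with 0 of 13 called over all genes or adjusted over the list alone (adjusted p = 0.0101, and adjusted p = 0.578 with an estimated correlation). TTR was at 2.37 (SE 1.12, adjusted p = 0.372).

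Of the 20 panel genes tested with dopamine, FOSB was the 1 that was called. The redox genes TXNRD1 (log2 fold change 0), SLC7A11 (-0.02), SOD2 (-0.03), HMOX1 (0.32) and NQO1 (0.34) had adjusted p from 0.223 to 0.997, and the dopamine receptor gene DRD2 was at -0.13 (adjusted p = 0.801). The monoamine oxidase gene MAOA was at -0.24 (adjusted p = 0.219) and the tyrosine hydroxylase gene TH at 0.51 (adjusted p = 0.468). For genes changed, dopamine vs control, the count of 133 became 489 with DESeq2, 540 in a fit with only these groups, and 590 with voom. It was 87, 7 and 100 without dopamine 1, 2 and 3, and 18, 37 and 8 without control 1, 2 and 3. HSPA6 lost its call in 4 of 12 alternatives (adjusted p up to 0.103), ADM in 6 (0.167), NKX2-2 in 7 (0.245), ATF3 in 5 (0.162) and GDF15 in 7 of 11 (0.161), mostly with a library left out. CCDC9 and FTL kept theirs in each fit, while the NRF2 list lost its call without control 2 (adjusted p = 0.0672) and choroid plexus without control 1 (0.148). The list nuclear oxidative phosphorylation genes, dopamine vs control, lost it without dopamine 1 (0.19) or control 2 (0.0879).

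**Figure D1:**
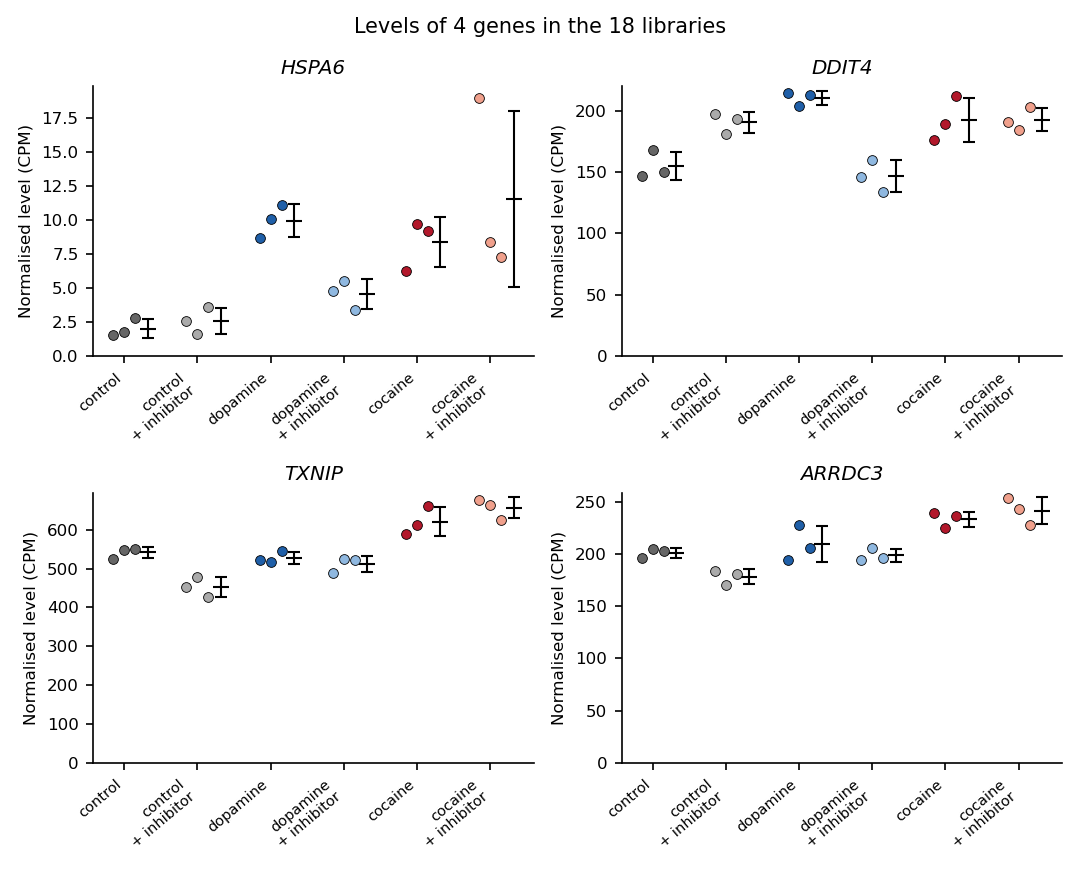
CPM of HSPA6, DDIT4, TXNIP and ARRDC3 in each of the 18 libraries by group, with points for libraries and the mean ± SD beside them. HSPA6 averaged 2.04 CPM in control against 9.98 with dopamine and 8.42 with cocaine, and DDIT4 was at 210 with dopamine and 147 with dopamine + inhibitor.

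Cocaine against control asked the same question for cocaine. Lists of genes of synapses, neurotransmitter receptors and interneurons were lower with cocaine, and lists of ribosomal, cell cycle and stress genes higher, under the preset correlation between genes. Of the 19 lists that passed, 0 did so with an estimated correlation (adjusted p of 0.215 to 0.55). The metabotropic glutamate receptor gene GRM5 (chromosome 11, 88504642 to 89065982) fell from 128 ± 8.63 to 76 ± 12.7 CPM (SD, n = 3; log2 fold change -0.75, SE 0.12, adjusted p = 0.0194). DLX6, an interneuron transcription factor (chromosome 7, 97005553 to 97011040), fell from 16.9 ± 1.09 to 8.13 ± 2.66 CPM (adjusted p = 0.0365). HSPA6 rose to 8.42 ± 1.85 CPM (fold change 4.12, adjusted p = 0.0217). Over all genes 818 were called, 328 higher and 490 lower, with a median absolute log2 fold change of 0.333, and 47 changed by at least 1 on the log2 scale.

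Further rises were in GEM, a small GTPase gene (1.39, SE 0.29), the growth factor gene IGF2 (1.25, SE 0.25), HIST1H1C (1.05, SE 0.24), the chaperone gene HSPA1A (0.97, SE 0.24), the mitochondrial carrier gene UCP2 (0.9, SE 0.24) and the pericyte gene RGS5 (0.85, SE 0.2). The mitotic genes HMMR and PBK rose by 1.21 (SE 0.29) and 0.86 (SE 0.23). HMGB2, a chromatin protein of dividing cells (chromosome 4, 173331376 to 173334358), went from 44.4 ± 2.15 to 86.4 ± 25.7 CPM (adjusted p = 0.0426). Falls were in the brain matrix gene TNR (chromosome 1, 175315194 to 175743595; 44.8 ± 4.3 to 25.2 ± 2.35 CPM), MUC3A (-0.9), the thyroid hormone deiodinase gene DIO3 (-0.86), the transcription factor gene TAL1 (-0.86), KIF26B (-0.84), SYNDIG1L (-0.83), COL15A1 (-0.83) and OTOF (-0.8), with adjusted p from 0.0194 to 0.038.

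All 28 presynaptic and synaptic genes were negative with cocaine (median -0.3), and 10 fell, or 20 adjusted over the list alone (adjusted p = 1.59e-12, and adjusted p = 0.215 with an estimated correlation). Among them were the vesicle priming gene UNC13A (-0.44), the active zone gene BSN (-0.39), the scaffold gene SHANK1 (-0.4) and NLGN3 (-0.3). All 20 glutamate receptor genes were negative (median -0.4), and 6 fell, or 11 adjusted over the list alone (adjusted p = 8.94e-09, and adjusted p = 0.215 with an estimated correlation). They included GRIK3 (-0.68), GRIA3 (-0.56) and GRM3 (-0.43). All 13 GABA receptor genes were negative (median -0.38), and 5 fell, or 11 adjusted over the list alone (adjusted p = 1.67e-08, and adjusted p = 0.215 with an estimated correlation). Among them were GABBR2 (-0.4), GABRG3 (-0.59), GABRB1 (-0.46) and GABBR1 (-0.29). The ventral forebrain and interneuron list had a median of -0.66, with 4 of 20 lower and 10 adjusted over the list alone (adjusted p = 2.31e-05, and adjusted p = 0.215 with an estimated correlation). Besides DLX6 these were the GABA transporter gene SLC32A1 (-0.68), the GABA-synthesizing enzyme gene GAD2 (-0.64) and CALB2 (-0.61). Pan-neuronal genes had a median of -0.19, with 2 of 16 lower, MAPT (-0.42) and DCX (-0.31), and 4 adjusted over the list alone (adjusted p = 0.000161, and adjusted p = 0.306 with an estimated correlation).

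Ribosomal protein genes were all positive (43 of 43, median 0.26), and 27 rose, or 41 adjusted over the list alone (adjusted p = 2.42e-22, and adjusted p = 0.215 with an estimated correlation). RPL23 rose by 0.38 and RPS14 from 376 ± 23.4 to 469 ± 34.5 CPM. Cell cycle genes were all positive (25 of 25, median 0.77). PCNA (0.42) and MCM6 (0.32) rose, and 23 passed adjusted over the list alone (adjusted p = 8.07e-11, and adjusted p = 0.306 with an estimated correlation). The mitotic kinase gene AURKB was at 1.23 (SE 0.34, adjusted p = 0.0524), and in cocaine 1, 2 and 3 MKI67 was at 45.7, 72.2 and 108 CPM. Of 17 p53 targets 5 rose, or 12 adjusted over the list alone, among them the cell cycle inhibitor gene CDKN1A (82.9 ± 5.9 to 125 ± 12.2 CPM), BBC3 (0.45) and TP53INP1 (0.33) (median 0.33, adjusted p = 7.27e-08, and adjusted p = 0.215 with an estimated correlation).

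In the unfolded protein response list 4 of 15 genes rose, or 10 adjusted over the list alone, with HSPA5 at 0.3 and HSP90B1 at 0.26 (median 0.24, adjusted p = 5.87e-07, and adjusted p = 0.215 with an estimated correlation). HSPD1 (0.22) and HSPA1A were called among 13 heat shock genes, and 8 adjusted over the list alone (median 0.16, adjusted p = 0.000161, and adjusted p = 0.215 with an estimated correlation). The integrated stress response list had SHMT2 (0.47) and DDIT4 (0.31) called among 18, and 4 adjusted over the list alone (median 0.14, adjusted p = 0.00245, and adjusted p = 0.282 with an estimated correlation). ROS producing and scavenging enzymes had GPX8 (0.74) and TXNIP (0.2), an inhibitor of thioredoxin, called among 24, and 10 adjusted over the list alone (median 0.11, adjusted p = 0.000749, and adjusted p = 0.215 with an estimated correlation). Of 21 NRF2 targets FTL (0.33) rose, and 3 adjusted over the list alone (median 0.09, adjusted p = 0.0148, and adjusted p = 0.215 with an estimated correlation). SDHD (0.31) rose among 34 nuclear oxidative phosphorylation genes, and 4 adjusted over the list alone (median 0.09, adjusted p = 2.31e-05, and adjusted p = 0.273 with an estimated correlation). Metallothioneins had a median of 1.01 with 0 of 6 called and 1 adjusted over the list alone (adjusted p = 0.0271, and adjusted p = 0.331 with an estimated correlation). MT1G was at 1.63 ± 1.25 against 0.0241 ± 0.0417 CPM (adjusted p = 0.0516).

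Markers of other cell types moved with cocaine beside these lists. Choroid plexus genes had a median of 1.23, with AQP1 (1.42, SE 0.37) called among 13 and 9 adjusted over the list alone (adjusted p = 0.00013, and adjusted p = 0.297 with an estimated correlation). The radial glia list, with VIM (0.38) called among 17 and 3 adjusted over the list alone, had a median of 0.2 (adjusted p = 0.0271, and adjusted p = 0.331 with an estimated correlation). Mesenchyme and matrix genes were at a median of 0.23 with 0 of 20 called over all genes or adjusted over the list alone, and eye and pigment genes at 0.85 with 0 of 8 called and 1 adjusted over the list alone (adjusted p = 0.0252 each, and adjusted p = 0.55 and 0.316 with an estimated correlation). Outside lists that passed, the keratin genes KRT5 (1.76, SE 0.43) and KRT14 (1.42, SE 0.36) rose from under 1 CPM in control, and EMX1, a dorsal forebrain factor, fell (-2.6, adjusted p = 0.0194). The dorsal forebrain list did not fall with it. Its mean log2 CPM was 3.05, 3.24 and 3.44 with cocaine against 2.82, 3.26 and 3.03 in the controls. The NRF2 list lost its call without control 2 (adjusted p = 0.0586), metallothioneins without cocaine 1 (0.16) or control 2 (0.076), and the list radial glia and neural progenitors, cocaine vs control, without cocaine 2 (0.0888), cocaine 3 (0.0647) or control 1 (0.056). The list mesenchyme and extracellular matrix, cocaine vs control, lost it without cocaine 3 (0.173) or control 2 (0.0567), and the list eye and pigment cells, cocaine vs control, without cocaine 2 (0.0562) or control 2 (0.0876).

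Of the 20 panel genes tested with cocaine, MAOA fell from 63.1 ± 2.27 to 48.5 ± 4.18 CPM (adjusted p = 0.0308) and TXNIP rose from 541 ± 13.5 to 621 ± 37.5 CPM (adjusted p = 0.0491). The TXNIP call was lost in 8 of 12 alternatives, among them RLE size factors, no filter and removal of the length trend (adjusted p up to 0.278), and that of MAOA in 5 (up to 0.2). NQO1 was at 0.4 (adjusted p = 0.0756), FOSB at 0.67 (adjusted p = 0.253) and DRD2 at -0.2 (adjusted p = 0.51). For genes changed, cocaine vs control, the count of 818 became 1648 with DESeq2, 1583 in a fit with only these groups, 2352 with voom and 333 with the length trend removed. It was 1121, 1 and 0 without cocaine 1, 2 and 3, and 0, 0 and 226 without control 1, 2 and 3. GRM5, RPS14 and HSPA6 lost their calls without cocaine 2 or 3 or control 1 or 2 (adjusted p up to 0.173), and DLX6 lost its call without these, without control 3 and with no filter (up to 0.2). Other calls were less stable. HMGB2, GAD2, GRIA3 and AQP1 lost theirs in 8 of 12 alternatives, and HMMR, PBK, CALB2, GRM3 and HSPA1A in 7 (up to 0.247). No filter and removal of the length trend were among these for each gene. PCNA, DCX, DIO3, GABBR1, GABRB1, DDIT4 and HIST1H1C lost theirs in 6, removal of the length trend among them.

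**Figure D2:**
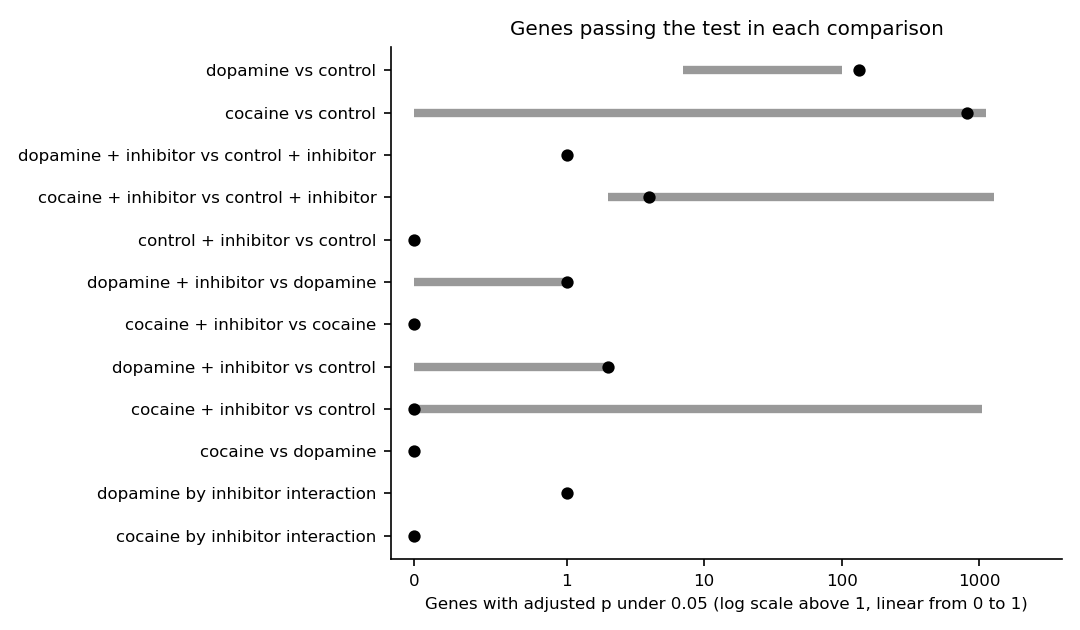
Number of genes called at an adjusted p under 0.05 in each of the 12 comparisons (black points, on an axis that is linear near 0 and logarithmic beyond), with the range when 1 library is left out (grey bars). Cocaine against control has the highest count, 818, with a range of 0 to 1121, and dopamine against control has 133, with a range of 7 to 100.

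**Figure D3:**
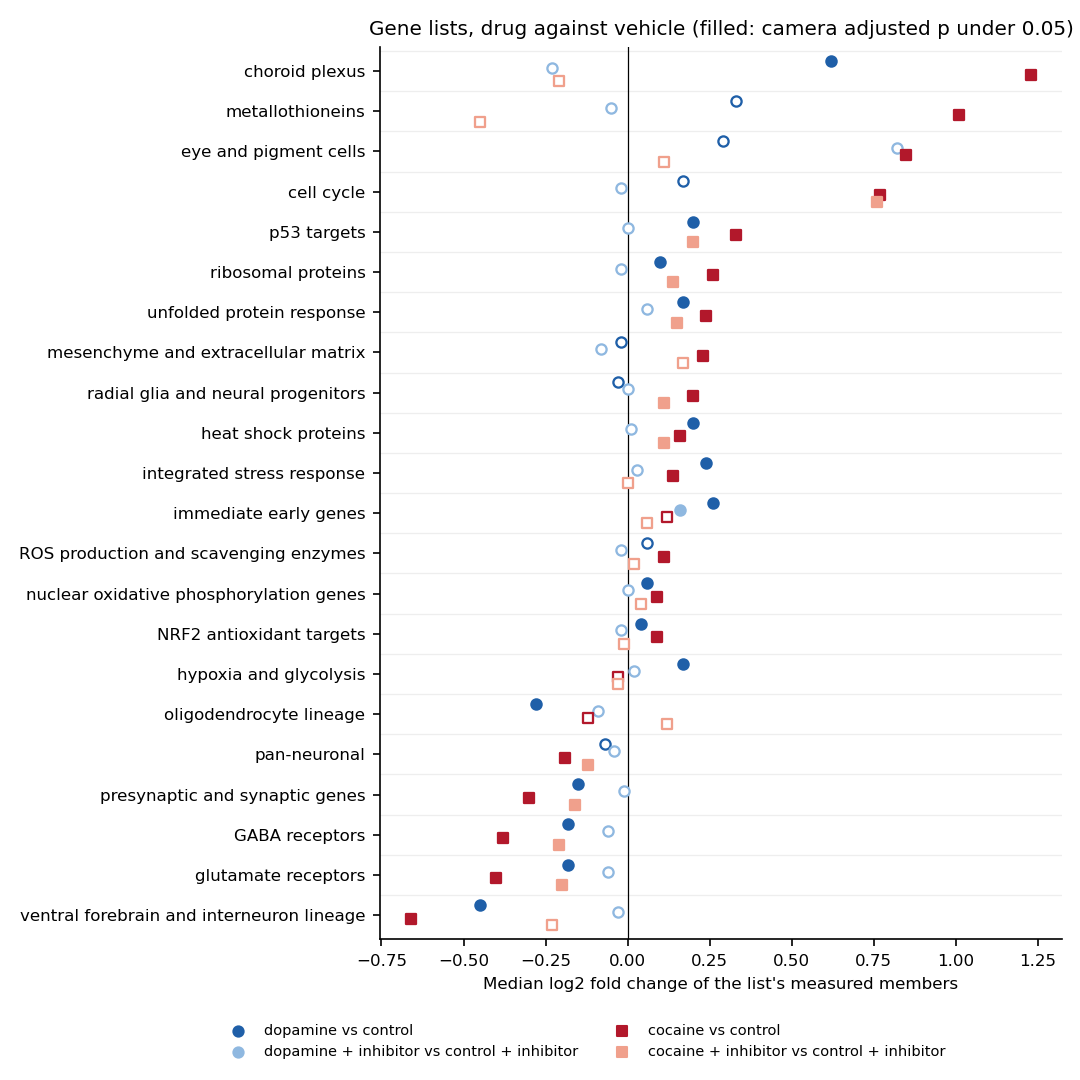
Median log2 fold change of each gene list that passed camera with dopamine or cocaine, for both drugs with and without the inhibitor, where filled points have an adjusted p under 0.05 with the preset correlation. Ventral forebrain genes lie lowest with cocaine (-0.66) and choroid plexus genes highest (1.23).

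With the inhibitor present in both arms, few genes were called for dopamine. The control + inhibitor libraries were uneven, with a chi-square per gene of 14.2, 5.5 and 18.1 between pairs. The count of calls is therefore no measure of an inhibitor effect. BIRC7, an inhibitor of apoptosis, was the 1 gene called, at 1.15 ± 0.0449 against 0.206 ± 0.0113 CPM (n = 3; log2 fold change 2.45, adjusted p = 0.0191), a level under the minimum of the naming rule, so it was chosen after its values were seen. The immediate early list had a median of 0.16, with 0 of 17 called over all genes or adjusted over the list alone (adjusted p = 0.00199, and adjusted p = 0.393 with an estimated correlation), and ATF3 was at 0.39 (SE 0.16, adjusted p = 0.887). Genes at an unadjusted p under 0.05 numbered 1056 against 946 expected by chance. DESeq2 called 6 genes and voom 2. The BIRC7 call was lost with only the groups compared and with each of the 6 libraries left out (adjusted p up to 0.224), and the immediate early list lost its call without dopamine + inhibitor 2 (adjusted p = 0.098).

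Whether the inhibitor changed the response to dopamine was tested by the interaction, and dopamine + inhibitor was also compared with dopamine. DDIT4 was the gene that differed: it was at 155 ± 11.1 CPM in control, 190 ± 8.18 in control + inhibitor, 210 ± 5.55 with dopamine and 147 ± 13.2 with dopamine + inhibitor (n = 3 each). Its dopamine effect differed by -0.82 (SE 0.1) on the log2 scale between the arms with and without the inhibitor (interaction, adjusted p = 0.00457), and the call remained in each alternative, from -0.88 to -0.76. DDIT4 was also the 1 gene called between dopamine + inhibitor and dopamine (-0.52, SE 0.07, adjusted p = 0.0208). That comparison also holds any effect of the inhibitor alone, so it does not by itself show a changed response to dopamine. In that comparison heat shock genes had a median of -0.18 (0 of 13 called, 7 lower adjusted over the list alone; adjusted p = 8.16e-08, and adjusted p = 0.124 with an estimated correlation). Unfolded protein response genes had -0.16 (0 of 15, 7 lower adjusted over the list alone; adjusted p = 1.71e-08, and adjusted p = 0.214 with an estimated correlation). Cholesterol synthesis genes had a median of -0.16 (0 of 20, 10 lower adjusted over the list alone; adjusted p = 8.71e-10, and adjusted p = 0.214 with an estimated correlation). The sterol carrier gene STARD4 was at -0.41 (adjusted p = 0.0744). The cholesterol list was also lower with the inhibitor alone, and it was not among the lists that passed for the interaction. Ventral forebrain genes had a median of 0.22, cell cycle genes -0.14 and ribosomal protein genes -0.09, with 0 called over all genes or adjusted over the list alone (adjusted p = 0.0142, 0.033 and 6.3e-07, and adjusted p = 0.706, 0.957 and 0.765 with an estimated correlation). The list ventral forebrain and interneuron lineage, dopamine + inhibitor vs dopamine, lost its call without dopamine 2 (0.398) or dopamine + inhibitor 2 (0.084), and the list cell cycle, dopamine + inhibitor vs dopamine, without dopamine 1 (0.148), dopamine 2 (0.116) or dopamine + inhibitor 1 (0.68). Between dopamine + inhibitor and dopamine, DESeq2 called 34 genes and voom 13; for the interaction DESeq2 called 17. The DDIT4 call between dopamine + inhibitor and dopamine was lost without dopamine 1, 2 or 3 or dopamine + inhibitor 1 or 3, with adjusted p up to 0.304.

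With the inhibitor in both arms, cocaine left 4 genes called. TXNIP (chromosome 1, 145992435 to 145996579) rose from 453 ± 26 to 657 ± 27.2 CPM (n = 3; log2 fold change 0.54, SE 0.06, adjusted p = 0.000249). Its relative ARRDC3 rose from 178 ± 7.1 to 242 ± 13.3 CPM (adjusted p = 0.00428) and the transcription factor gene KLF10 from 39.2 ± 1.54 to 52.7 ± 3.39 CPM (adjusted p = 0.00488), while FAM13B fell from 108 ± 9.88 to 75.8 ± 6.73 CPM (adjusted p = 0.00488). In control without the inhibitor TXNIP was at 526, 548 and 551 CPM, so lower levels in control + inhibitor made up part of its difference. In all 3149 genes had an unadjusted p under 0.05. All 25 cell cycle genes were positive (median 0.76; 0 called, 21 adjusted over the list alone; adjusted p = 1.63e-12, and adjusted p = 0.454 with an estimated correlation). MKI67 was at 126, 43.5 and 84.3 CPM in cocaine + inhibitor 1, 2 and 3. All 20 cholesterol synthesis genes were positive (median 0.12; 0 called, 8 adjusted over the list alone; adjusted p = 1.38e-06, and adjusted p = 0.454 with an estimated correlation). FDFT1 was at 0.39 (adjusted p = 0.0729). The mean log2 CPM of the cholesterol list was 7.53, 7.39 and 7.38 in cocaine + inhibitor, against 7.21, 7.36 and 7.2 in control + inhibitor. It was 7.48, 7.44 and 7.44 in control without the inhibitor, so the difference went with low levels in control + inhibitor. Glutamate receptor genes had a median of -0.2 (0 of 20 called, 5 lower adjusted over the list alone; adjusted p = 5.54e-05, and adjusted p = 0.454 with an estimated correlation). GRM5 was at -0.5 (adjusted p = 0.143). Markers of other cell types moved too, and so did the replication-dependent histones, a list fixed as a check of quality and not as cell type markers. Pan-neuronal genes had a median of -0.12 and ciliated ependyma genes 0.3 (12 of 12 positive), radial glia genes 0.11 and replication-dependent histones 0.45 (5 of 5 positive), with adjusted p of 0.00982, 0.0132, 0.0425 and 0.0175 (0.602, 0.653, 0.579 and 0.454 with an estimated correlation). Of these, 0 members were called, and adjusted over the list alone 1 histone gene was higher. Without control + inhibitor 2 the calls of the list pan-neuronal, cocaine + inhibitor vs control + inhibitor (0.476), the list ciliated ependyma, cocaine + inhibitor vs control + inhibitor (0.363) and the list radial glia and neural progenitors, cocaine + inhibitor vs control + inhibitor (0.159) were lost. They were also lost without cocaine + inhibitor 3 (0.0821, 0.232 and 0.235), radial glia also without cocaine + inhibitor 1 (0.0593), and the list replication-dependent histones, cocaine + inhibitor vs control + inhibitor, without cocaine + inhibitor 1 (0.0624) or control + inhibitor 1 (0.0799). In all 15 lists passed, 9 higher and 6 lower, with adjusted p of 0.454 to 0.653 with an estimated correlation. DESeq2 called 313 genes, voom 8, no filter 9 and a fit with only these groups 0, where TXNIP had an adjusted p of 0.318. Without cocaine + inhibitor 2 the count was 1276, and without cocaine + inhibitor 1 it was 2.

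No gene passed between cocaine + inhibitor and cocaine: edgeR, DESeq2 and voom each called 0, with 608 at an unadjusted p under 0.05. The smallest p belonged to the potassium channel gene KCNA6 (0.22), the vitamin D hydroxylase gene CYP24A1 (-1.15), HKDC1 (0.84), the sodium channel subunit gene SCN4B (0.49) and LOC731075 (1.41), none of which passed (adjusted p = 1). Choroid plexus genes had a median of -0.66 (0 of 13 called over all genes or adjusted over the list alone; adjusted p = 0.00306, and adjusted p = 0.668 with an estimated correlation). Ribosomal protein genes had -0.09 (0 of 43 likewise; adjusted p = 9.48e-10, and adjusted p = 0.668 with an estimated correlation). Caudal identity genes had a median of -0.36, eye and pigment genes -0.44 and ciliated ependyma genes 0.25, again with 0 called either way (adjusted p = 0.00586, 0.0426 and 0.0286, and adjusted p = 0.668, 0.668 and 0.721 with an estimated correlation). The list caudal and hindbrain identity, cocaine + inhibitor vs cocaine, lost its call without cocaine + inhibitor 1 (0.477). The list eye and pigment cells, cocaine + inhibitor vs cocaine, lost it without cocaine 2 (0.123) or 3 (0.11) or cocaine + inhibitor 1 (0.193) or 2 (0.339), and the list ciliated ependyma, cocaine + inhibitor vs cocaine, without cocaine 2 (0.18) or 3 (0.11) or cocaine + inhibitor 1 (0.193) or 3 (0.526). The list choroid plexus, cocaine + inhibitor vs cocaine, lost its call without cocaine 1 (0.286) or cocaine + inhibitor 2 (0.0618), and the ribosomal list without cocaine 3 (0.16). The cocaine by inhibitor interaction called 0 genes with edgeR, 0 with voom and 1 with DESeq2, with 995 at an unadjusted p under 0.05. CYP24A1 (-2.09, SE 0.38), RARRES2 (-2.96, SE 0.59), the klotho gene KL (-2.85, SE 0.62), SCN4B (0.77, SE 0.18) and AKR1B10 (-2.1, SE 0.47) had the smallest p and did not pass (adjusted p of 0.513 to 0.918). The cocaine effects with and without the inhibitor were therefore not shown to differ for any single gene by edgeR.

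With the inhibitor alone the genes of cholesterol synthesis were lower as a group, under the preset correlation between genes only. All 20 were negative (median -0.19; 0 called over all genes, 10 lower adjusted over the list alone; adjusted p = 1.43e-18, and adjusted p = 0.179 with an estimated correlation). DHCR7 was at 153 ± 9.53 against 181 ± 5.3 CPM (-0.24), FDFT1 at -0.3 and the sterol sensor gene INSIG1 at -0.28 (adjusted p of 0.729 to 0.823). No gene passed with edgeR, 1081 had an unadjusted p under 0.05, and DESeq2 called 4 and voom 6. The smallest p were those of the channel gene HCN3 (-0.36), the fatty acid synthase gene FASN (859 ± 49.8 to 692 ± 31.7 CPM), DHCR7, TXNIP (-0.26) and DCAF4L1 (0.9), each with an adjusted p of 0.729. Choroid plexus genes had a median of 0.89 (0 of 13 called, 1 adjusted over the list alone; adjusted p = 5.06e-06, and adjusted p = 0.395 with an estimated correlation). Metallothioneins had 1.19 (0 of 6, 2 adjusted over the list alone; adjusted p = 0.000732, and adjusted p = 0.395 with an estimated correlation). The integrated stress response list had a median of 0.13 (17 of 18 positive, 0 called, 1 adjusted over the list alone; adjusted p = 0.000564, and adjusted p = 0.395 with an estimated correlation). Ventral forebrain genes had a median of -0.19 (0 of 20 called over all genes or adjusted over the list alone; adjusted p = 0.0155, and adjusted p = 0.608 with an estimated correlation). The list ventral forebrain and interneuron lineage, control + inhibitor vs control, lost its call without control 1 (0.109) or control + inhibitor 1 (0.157) or 3 (0.24). The metallothionein list lost its call without control + inhibitor 3 (adjusted p = 0.0718), the library in which MT1G was at 4.75 CPM.

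Against control without the inhibitor, dopamine + inhibitor raised the heparan sulfotransferase gene HS3ST3B1 from 12.2 ± 0.939 to 19.3 ± 2.1 CPM (n = 3; adjusted p = 0.0245) and BIRC7 from 0.164 ± 0.0639 to 1.15 ± 0.0449 CPM (adjusted p = 0.00572). These were the 2 genes called, and both lost their call with only the groups compared. DESeq2 called 35 and voom 30, and the count was 1 without dopamine + inhibitor 2 or 3 or control 2, and 0 without control 1 or 3. Metallothioneins had a median of 1.17 (0 of 6 called, 2 adjusted over the list alone; adjusted p = 0.000312, and adjusted p = 0.264 with an estimated correlation). Choroid plexus genes had a median of 0.61, ventral forebrain genes -0.25 and eye and pigment genes 1.43, with 0 called, and 4 eye and pigment genes higher adjusted over the list alone (adjusted p = 0.000194, 0.00957 and 0.017, and adjusted p = 0.505 each with an estimated correlation). The list eye and pigment cells, dopamine + inhibitor vs control, lost its call without dopamine + inhibitor 3 (0.531) or control 2 (0.121).

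Cocaine + inhibitor against control gave HSPA6 at 11.6 ± 6.49 against 2.04 ± 0.683 CPM, the netrin receptor gene UNC5A (-0.48), GABBR2 (-0.4), CHST2 (-0.53) and HSPA1A (1.36) with the smallest p, and none passed (adjusted p = 0.0823). Ribosomal protein genes had a median of 0.18 (0 of 43 called, 28 adjusted over the list alone; adjusted p = 5.82e-14, and adjusted p = 0.377 with an estimated correlation). Cell cycle genes had a median of 0.76 (0 of 25 called, 24 adjusted over the list alone; adjusted p = 1.03e-11, and adjusted p = 0.377 with an estimated correlation). Pan-neuronal genes had -0.17, ventral forebrain genes -0.51, choroid plexus genes 0.53, ciliated ependyma genes 0.38 and replication-dependent histones 0.68 (adjusted p = 9.23e-05, 5.93e-05, 0.0283, 0.00877 and 0.0229, and adjusted p of 0.324 to 0.558 with an estimated correlation). Of these 0 were called, and adjusted over the list alone 1 pan-neuronal and 4 ventral forebrain genes were lower and 1 histone gene higher. The list choroid plexus, cocaine + inhibitor vs control, lost its call without cocaine + inhibitor 3 (0.155) or control 1 (0.188), the list ciliated ependyma, cocaine + inhibitor vs control, without the same (0.155 and 0.312), and the list replication-dependent histones, cocaine + inhibitor vs control, without cocaine + inhibitor 1 (0.0658). For genes changed, cocaine + inhibitor vs control, edgeR called 0 with 3287 at an unadjusted p under 0.05. DESeq2 called 456, voom 156 and no filter 5. Without cocaine + inhibitor 2 edgeR called 1046, and without cocaine + inhibitor 3 it called 2.

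The drugs were also compared with each other. The control libraries enter that test only through the scaling, the expression filter and the shared estimate of the spread. Hypoxia and glycolysis genes were lower with cocaine than with dopamine (median -0.17; 0 of 27 called, 7 lower adjusted over the list alone; adjusted p = 4.69e-11, and adjusted p = 0.355 with an estimated correlation). ADM was at 5.94 ± 0.624 against 12.1 ± 2.45 CPM and the hexokinase gene HK2 at 307 ± 4.99 against 372 ± 5.86 CPM (n = 3; adjusted p = 0.289 and 0.237). Ribosomal protein genes were higher (median 0.18; 0 of 43 called, 22 adjusted over the list alone; adjusted p = 1.35e-16, and adjusted p = 0.355 with an estimated correlation). RPS6 was at 0.3 (adjusted p = 0.289). Cell cycle genes had a median of 0.56 (0 of 25 called over all genes or adjusted over the list alone; adjusted p = 4.89e-11, and adjusted p = 0.366 with an estimated correlation). Cell type markers also moved, with 0 members called over all genes or adjusted over the list alone. Medians were 0.62 for choroid plexus, -0.14 for pan-neuronal, 0.15 for radial glia, 0.33 for ciliated ependyma, 0.31 for mesenchyme and 0.51 for non-neural epithelium genes (adjusted p of 0.00159 to 0.0473, and adjusted p of 0.355 to 0.593 with an estimated correlation). Mesenchyme and radial glia kept their calls with any library left out. The list choroid plexus, cocaine vs dopamine, lost its call without cocaine 1 (0.592) or dopamine 3 (0.086), and the list pan-neuronal, cocaine vs dopamine, without cocaine 3 (0.052) or dopamine 1 (0.0724). The list ciliated ependyma, cocaine vs dopamine, lost it without cocaine 1 (0.268), dopamine 1 (0.136) or dopamine 3 (0.0639), and the list non-neural epithelium and endoderm, cocaine vs dopamine, without cocaine 1 (0.147), cocaine 2 (0.128) or dopamine 3 (0.161). No single gene passed with edgeR (2224 at an unadjusted p under 0.05), none with voom and 72 with DESeq2. NIT1 (0.33), PDXDC1 (-0.22), the vesicle coat gene SEC24A (-0.34), the hexosamine enzyme gene GFPT1 (-0.33) and SLC35E1 (-0.26) had the smallest p (adjusted p = 0.176).

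In the authors' deposited table for dopamine, 64 genes were listed, 42 higher and 22 lower, and the fold change here had the same sign for all 64, of which 14 were called here. The authors' tables rest on the same libraries and hold large fold changes only, and their comparators were matched to these libraries. The same sign in each of them is therefore no independent support. The largest values in the authors' deposited table were CDC27P9 (4.88), the B-cell and midbrain factor PAX5 (3.05), the midbrain factor EN2 (2.8), ABCA4 (2.57) and LINC00473 (2.39), and the lowest were the posterior identity genes HOXB8 (-3.71), HOXB5 (-3.51), HOXB6 (-3.37), HOXC8 (-3.22) and HOXB7 (-3.14). Of these 10, LINC00473 was called here (adjusted p = 0.0409). For cocaine the authors' deposited table listed 231 genes, 188 higher and 43 lower; 216 were tested here, all 216 with the same sign, and 45 were called. The authors' deposited table was led there by CERS6-AS1 (10.05), HOXD10 (7.75), HOXA9 (7.75), MT1G (5.84) and HOXC10 (4.65), and EMX1 (-2.6) was among the lowest. HOXA9 was at 0.0749, 23.6 and 2.25 CPM in cocaine 1, 2 and 3 and had an adjusted p of 0.129 here.

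With the inhibitor, the authors' deposited table for cocaine listed 72 genes, 53 higher and 19 lower, of which 71 were tested here, all 71 with the same sign, and 0 were called. In the authors' deposited table the neuronal determination genes NEUROG1 (3.04) and NEUROG2 (2.99) were among the highest, and NEUROG2 was at 143, 33.2 and 71.2 CPM in cocaine + inhibitor 1, 2 and 3. For dopamine with the inhibitor the authors' deposited table listed 12 genes, of which 10 were tested, all 10 with the same sign, and 1 was called. After CERS6-AS1 (5.37), the highest in the authors' deposited table were the pigment cell genes MLANA (4.66), PMEL (4.34) and TYRP1 (3.95). The inhibitor alone had 12 genes in the authors' deposited table, led by MT1G (6.06), CDC27P9 (5.27), HOXA9 (4.99) and TTR (2.91), all 12 with the same sign here and 0 called. Called here and absent from the authors' deposited tables were 119 genes for dopamine and 773 for cocaine; in all, 14 of 133 and 47 of 818 called genes changed by at least 1 on the log2 scale.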

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

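The tests of the length trend, the neuron share, 1 library, the slope and the shares of the dopamine stress genes were chosen only after the result was seen, where the bounds for the length trend and the slope were set before their values were known. In the neuron share test the bound against the explanation was also replaced after its value was seen. The first bound asked whether the pan-neuronal median lay nearer 0 than the synaptic and receptor median with any 1 library left out, and it was met in every fit, which would have argued against the explanation. It was replaced because a loss of the neurons richest in synaptic transcripts would lower synaptic genes more than pan-neuronal ones.

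Of 61 genes of synapses and transmitter receptors 21 were called lower with cocaine, such as GRM5 and UNC13A, and the lists passed with the preset correlation only (adjusted p = 0.215 each with an estimated correlation). A trend of counts on transcript length between libraries was weighed; genes lower with cocaine had a median relative length of 1.8, against 0.631 for higher genes. After its removal 87% of the median of the called members was left (76.2% to 87.6% with 1 library left out; -0.4 to -0.35), which argues against it as the whole cause, while 9 of the 21 stayed called and the gene count went from 818 to 333. A lower share of neurons could lower the same genes: the pan-neuronal median was -0.19 (16 genes) against -0.32, a gap of 0.13 (0.11 to 0.2), which leaves it open under the replaced bound. Cell type shares were not measured.

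With the inhibitor in both arms, 4 genes were called for cocaine against 818 without it, TXNIP and ARRDC3 among the 4. The library cocaine + inhibitor 2 may account for much of that gap, since the count was 1276 without it and 2 and 5 without cocaine + inhibitor 1 and 3. With voom and sample quality weights, however, the count also stayed far lower with the inhibitor than without it. A smaller response to cocaine under the inhibitor would give a slope well under 1 between the responses. The slope was 0.77, and from 0.48 to 1.09 with 1 library left out, which leaves this open. Without cocaine + inhibitor 2 it was 1.01, so a wider spread and a smaller response in that library are not told apart. The slope did not hang on that library alone. Its lowest value came without control + inhibitor 2 (0.48) and its highest without cocaine 3 (1.09). The counts of 4 and 818 are therefore no measure of an inhibitor effect.

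The 73 members of the stress lists that were higher with dopamine, most of which did not pass singly, had a median of 0.19 without the inhibitor and 0.03 with it. Over all members, higher levels in control + inhibitor than in control made up 24.4% of the difference between the dopamine effects (12.3% to 31.5% with 1 library left out), and lower levels in dopamine + inhibitor than in dopamine 58.1% (50% to 75.8%, the lowest just under the bound of 50% before rounding). The lists differed. For the unfolded protein response, heat shock and hypoxia lists (55 members) the shares were 18.9% (1.65% to 21.8%) and 72.5% (58.4% to 87.9%). Lower levels in dopamine + inhibitor thus made up the larger share in each fit. For the integrated stress response list (18 members) the shares were 60.2% (32.7% to 90.5%) and 39.1% (30.4% to 47.3%), so neither was the larger in each fit. The share from dopamine + inhibitor was under the bound of 50% in each fit. It was still the larger share without control + inhibitor 1 (44.2% against 32.7%) or control + inhibitor 3 (44.9% against 44.1%). For the list member DDIT4 it was -0.52 of -0.82. The interaction lists did not pass with an estimated correlation, so the difference itself remains uncertain. The stress lists were also picked because they were higher with dopamine than in control in these libraries. That pick by itself favors high dopamine and low control values, so the shares do not decide the source and leave it open.

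DDIT4 differed in its dopamine effect between the arms with and without the inhibitor (-0.82). For the dopamine by inhibitor interaction, median differences were -0.11 for NRF2 targets (adjusted p = 0.177 with an estimated correlation), -0.21 for the integrated stress response (0.175), -0.2 for the unfolded protein response (0.378) and -0.23 for heat shock genes (0.175). They were -0.11 for hypoxia and glycolysis, -0.19 for p53 targets, -0.12 for ribosomal proteins, 0.17 for glutamate receptors, 0.14 for synaptic genes and -0.83 for choroid plexus (0.67 each), and 0.38 for ventral forebrain genes (0.561). For cocaine by inhibitor they were -0.08 for NRF2 targets, -1.46 for metallothioneins, -0.19 for the integrated stress response, 0.21 for cholesterol synthesis, -1.62 for choroid plexus and -0.49 for cartilage (0.25 each). They were -0.12 for ROS enzymes (0.49), -0.43 for non-neural epithelium (0.409), and -0.11 for p53 targets and -0.24 for astrocytes (0.557 each). They were -0.07 for oxidative phosphorylation, -0.13 for ribosomal proteins, 0.13 for glutamate receptors, 0.17 for GABA receptors, 0.14 for synaptic genes and 0.36 for ventral forebrain genes (0.529 each). Each list had 13 alternatives, the estimated correlation among them. For cocaine by inhibitor, astrocytes lost the call in 8, and p53 targets, non-neural epithelium and cartilage in 7 each. ROS enzymes and glutamate receptors lost it in 5 each. For dopamine by inhibitor, choroid plexus and glutamate receptors lost it in 5 each. The other lists lost it less often.

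The libraries of each comparison were also regrouped to ask how many genes other splits call. Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. Dopamine called 133 genes against a highest other count of 0, cocaine 818 against 0, and dopamine with the inhibitor in both arms 1 against 0. Dopamine with the inhibitor called 2 against 0 from control, and 1 against 0 from dopamine alone. In each of these, 1 split of 10, the real one, reached the real count. For cocaine with the inhibitor in both arms, 2 of 10 splits reached 4 genes and another split called 22. The remaining comparisons called 0 genes, which all 10 splits reached. For the dopamine by inhibitor interaction 9 of 100 splits called at least 1 gene, the real one with DDIT4 among them, and the highest called 155. For cocaine by inhibitor all 100 reached 0 and the highest called 2689. Labels were exchanged within each arm separately, so a split can keep or reverse the drug effect in 1 arm. High counts can therefore hold a drug effect, and which splits gave them was not examined. These splits cannot decide whether chance gave the DDIT4 call, so chance is not excluded.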

How the results depend on the processing

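Removal of the length trend was added after the data were seen, and the other alternatives were planned. No paired analysis was possible because the libraries share no replicate number between groups.

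Gene counts moved most with the tool and with the library left out, and the cause was not tested. For genes changed, dopamine vs control, the 133 calls (105 higher, 28 lower) became 489 with DESeq2 (295, 194), 540 with only the groups compared (273, 267) and 590 with voom (348, 242), and 7 to 100 with 1 library left out. For genes changed, cocaine vs control, the 818 calls became 1648, 1583 and 2352 by the same alternatives, 333 with the length trend removed, and 0 to 1121 with 1 library left out. RLE size factors left all 12 counts within 1.5 times.

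With the inhibitor in both arms, dopamine had 1 call, against 6 with DESeq2, 2 with voom and 0 with any library left out. Cocaine had 4, against 313 with DESeq2, 9 with no filter, 8 with voom, 0 with only the groups compared, and 2 to 1276 with 1 library left out. The inhibitor alone had 0, against 4 with DESeq2 and 6 with voom. Dopamine + inhibitor against dopamine had 1, against 34 with DESeq2, 13 with voom, 3 with no filter, 3 with only the groups compared, and 0 to 1 with 1 library left out. Dopamine + inhibitor against control had 2, against 35 with DESeq2, 30 with voom, 3 other genes with only the groups compared, and 0 to 2 with 1 library left out. The genes changed, cocaine + inhibitor vs control, numbered 0, against 456 with DESeq2, 156 with voom, 5 with no filter, and 0 to 1046 with 1 library left out. Cocaine against dopamine had 0 and 72 with DESeq2, the dopamine interaction 1 and 17 with DESeq2, and the cocaine interaction 0 and 1 with DESeq2.

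Of the 157 gene list results that passed over the 12 comparisons, 2 kept their call with an estimated correlation, the integrated stress response and heat shock lists for dopamine, and 155 lost it. With 1 library left out, 924 of the list tests kept their call, 178 lost it and 2 turned direction. Both were of the list presynaptic and synaptic genes, cocaine + inhibitor vs cocaine, which was higher in all libraries together; its adjusted p ran from 0.000162 without cocaine 1 to 0.91 without cocaine 3 and 0.919 without cocaine + inhibitor 2, and without either of the latter the direction was down.

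The genes that turned direction, or lay at 0, were panel genes and the metallothionein gene MT1E, and none passed the test. For dopamine TXNRD1 (0) was 0 with voom, SLC7A11 (-0.02) 0.01 with the length trend removed, and GPX3 (0) 0 with no filter and 0.04 with voom. For cocaine SLC7A11 (0) was -0.03 and SOD2 (0.01) 0 with voom, GPX3 (0.02) -0.02 with the length trend removed, and MT1E (1.4) -0.63 with voom. For the cocaine interaction MT1E (-1.98) was 0.15 with voom. With 1 library left out, dopamine values ran from -0.18 to 0.39 for DRD5, -0.06 to 0.2 for NPAS4, -0.03 to 0.02 for TXNRD1, -0.08 to 0.03 for SLC7A11, -0.07 to 0.04 for SOD2, -0.08 to 0.1 for GPX3 and -0.14 to 0.1 for MT2A. Cocaine values ran from -0.28 to 0.29 for DRD5, -0.06 to 0.06 for SLC7A11, -0.04 to 0.07 for SOD2 and -0.16 to 0.13 for GPX3.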

Other observations

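Some genes were called with both drugs. HSPA6, HIST1H1C, FTL, HSPA5 and DDIT4 rose with both drugs and COL15A1 fell with both, and in all 47 genes were called for both, 27 higher and 20 lower, each with the same sign. Both comparisons used the same 3 control libraries, which by themselves tie the fold changes together. Across genes the fold changes had a correlation of 0.51, against 0.49 on average and 0.56 at most in 20 simulations with no drug effect. The simulations called 0 genes for both drugs. The covariance was 0.0636 against 0.038 on average and 0.0458 at most in the simulations. These drew each gene separately, so they hold no shift shared by many genes, such as a difference in cell type markers between controls. Libraries without a drug effect could therefore exceed the simulated values, and an excess is not established. The controls were not split between the comparisons, so some or all of the higher covariance and of the shared calls may come from the shared controls.

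Genes called without the inhibitor mostly kept their sign with it. For dopamine 113 of 133 did (85%), with a median of 0.14 for higher genes against 0.38 without the inhibitor, and of -0.07 for lower genes against -0.45. For cocaine 779 of 818 did (95.2%), with 0.16 against 0.31 and -0.19 against -0.36. Values picked because they passed in 1 set are larger there than in another set by selection alone, so these medians do not show a weaker response with the inhibitor.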
